A study of Nicotiana benthamiana with 12 samples.

How the data were processed

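Total RNA of agroinfiltrated leaves was extracted with a column kit and DNase and sequenced on an Illumina HiSeq instrument, per the labels, with 6 leaves per construct, each from its own plant, and 2 leaves pooled in each library. Each of the 12 files gives, per the file headers, the authors' count of uniquely assigned reads for each gene and the RPKM value they computed from it, the reads per kilobase of gene model per M reads assigned to genes. The authors also list a percent coverage of each gene model, which was not used here. The aligner, the genome build and the annotation version are not given in the sources used here. Genes with 0 reads are left out of each file, so absent genes were set to 0; the files list 44418 to 45156 genes and 56832 in all. RPKM values recomputed from the deposited counts equalled those listed in 12 of 12 files (relative tolerance 1e-09). Gene names are the descriptions in the files, the best hits in other species, and 7937 genes (14.0%) have none.

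Samples were grouped by their titles. The construct labels of the SNARE hairpin libraries read MtVAMP721e, MtVAMP722e and MtVAMP723e for replicates 1, 2 and 3 in both groups, while the series' design names MtVAMP721e alone, and the libraries were taken as replicates of 1 hairpin. The replicates are separate pools of leaves, so p-values cover differences between pools. Library totals ran from 5.64 to 6.59 M reads, with means of 6.47 (empty vector), 6.35 (SNARE hairpin), 6.36 (CST) and 5.79 M (CST and SNARE hairpin). A count of 3 reads in a gene model of 1 kb corresponds to 0.532 RPKM at the lowest depth and 0.456 at the highest. Replicate pairs differed beyond sampling noise, with 1.9 to 6.47 as chi-square per gene.

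The main test, chosen before the data were examined, was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment on the deposited counts, in 1 fit over the 12 libraries. It used a mean for each group, TMM factors (0.946 to 1.058), edgeR's filter on low counts, and a threshold of 0.05. The filter kept 31469 genes with 99.3% of the reads, and the common biological coefficient of variation was 0.114. The comparisons were the 4 simple effects, the joint effect and the interaction. Errors of fold changes are standard errors derived from the test statistic, and levels are mean RPKM over 3 libraries. Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and with an estimated one, adjusted over the 35 lists with 5 or more tested genes, and with fry; calls were also counted adjusted over the list alone.

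The 38 lists were fixed by words in the descriptions: VAMP7 and synaptobrevin, other SNAREs, vesicle traffic, terpene synthases, the mevalonate and plastid MEP pathways, capsidiol enzymes, ABC transporters, lipid transfer proteins, cuticle, cell wall, pathogenesis-related proteins, WRKY factors, jasmonate, ethylene, salicylate, phenylpropanoids, glutathione transferases, UDP-glycosyltransferases, cytochromes P450, peroxidases, heat shock proteins, photosynthesis, tetrapyrroles, ribosomal proteins, histones and cell cycle, senescence, RNA silencing, receptor-like kinases, calcium, sugar transport, aquaporins, and markers of guard cells, trichomes, phloem and xylem, meristem and root, bacteria and virus. Genes with an orthology label of VAMP72 or VAMP7, called VAMP72-like here, were added after values were seen. So were PsbO genes, proteasome genes, and 750 annotation terms of 10 to 500 tested genes. Named genes were the fixed VAMP7 list whatever its p, and the 8 largest rises and the 8 largest falls that passed. These needed groups that do not overlap, at least 5 RPKM in the higher group and an informative description, with 1 gene per description. Up to 2 risers and 2 fallers of each list were added, or its most expressed gene where none passed, and for the interaction the 5 smallest adjusted p. The text leaves some out for length and says where genes were added.

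On simulated counts with 30896 genes in the fit, the test called 82.1% of genes with a log2 change of 1 and 23.9% of those with 0.5 for the SNARE hairpin without CST. These shares were 63.6% and 13.4% for CST without the SNARE hairpin, 67.7% and 20.2% for the SNARE hairpin with CST, 80.6% and 26.8% for CST with the SNARE hairpin, 68.7% and 19.2% for both together, and 46.5% and 5% for the interaction. Changes were planted only in genes above a minimum mean count, so these shares do not cover genes with fewer reads. Among simulated unchanged genes 7 to 19 were called per comparison. Lists shifted by 0.5 were called in 8 of 8 tests, and unshifted lists in 0 of 52. These lists held random genes simulated independently, so false calls of lists with correlated genes were not measured.

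Alternatives were a replicate block, DESeq2 1.42.0, upper-quartile scaling, other filters, fits of the compared groups only, limma-trend on log2(RPKM + 0.5) and log2(RPKM + 0.1) for genes with 1 RPKM in at least 3 libraries, libraries without photosynthesis and the 50 most abundant genes, and leaving out each library. Library-total scaling and thinning to the lowest total were added after seeing the data. RPKM values are themselves scaled by library totals, so limma-trend on them and library-total scaling are not independent alternatives. Overlaps between comparisons that share libraries were set beside simulated unchanged groups.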

Results

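Leaves of Nicotiana benthamiana, a tobacco relative used for transient expression, carried 1 of 4 pairs of constructs delivered by Agrobacterium. The pairs form a layout of 2 factors. These are a caryophyllene synthase (CST), an enzyme that makes a sesquiterpene, and a hairpin against the v-SNARE gene MtVAMP721e, each present or absent. Many VAMP72 proteins, though not all, sit on secretory vesicles and take part in their fusion with the plasma membrane. The empty vector with a DsRed hairpin, the SNARE hairpin with the DsRed hairpin, CST with the DsRed hairpin, and CST with the SNARE hairpin were each represented by 3 libraries. Each library pooled 2 leaves taken 7 days after infiltration from 5-week-old plants. The group with CST and the SNARE hairpin was the 1 group without the DsRed hairpin, so each comparison that involves it also changes that construct. Libraries held between 5.64 and 6.59 M reads assigned to genes, and 31469 genes were tested. Replicates correlated at 0.969 to 0.983 (Pearson r of log2 counts per M reads, CPM, across genes, which are not independent). Libraries of different groups could correlate as highly. SNARE hairpin replicate 2 reached 0.977 with CST replicate 2, against 0.974 with each of its own replicates. Empty vector replicate 3 reached 0.976 with that CST library, against 0.976 and 0.979 with its own replicates. The CST and SNARE hairpin libraries correlated at no more than 0.954 with other groups. In a principal component analysis the first component, with 35.3% of the variance, placed the CST and SNARE hairpin libraries at scores of 61.9 to 74 and the other libraries at -34.5 to -11.3. The second component, with 21.6%, ran from -40.9 in an empty vector library to 68.8 in CST replicate 1, and libraries of 1 group were spread along it.

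The hairpin lowered VAMP72-like transcripts in every library that carried it. NbS00060093g0001.1, a VAMP727-like gene, lay at 25.5, 26 and 30 RPKM in the empty vector libraries (replicates 1 to 3) and at 42.7, 36.7 and 36.1 with CST. It lay at 4.68, 5.65 and 5.7 RPKM with the SNARE hairpin and at 4.71, 5.82 and 6.61 with both. NbS00004447g0302.1 lay at 32.2 to 36.6 and 37.9 to 44.2 RPKM without the hairpin and at 5.36 to 6.76 and 7.73 to 9.03 with it. For NbS00012174g0011.1 the ranges were 24.8 to 30 and 23.4 to 29.4 RPKM against 2.85 to 4.15 and 2.87 to 5.94. Summed over the 20 tested VAMP72-like genes, the groups had 442.8 ± 54.1 (empty vector), 156.2 ± 10.2 (SNARE hairpin), 527.3 ± 26.2 (CST) and 167.9 ± 20.1 (CST and SNARE hairpin) summed CPM (mean ± SD, n = 3). Of the 20 genes 9 fell and 0 rose with the SNARE hairpin without CST, 11 and 0 adjusted over the list alone (edgeR; camera p = 3.6e-78, and p = 7e-08 with an estimated correlation). With CST 11 fell and 0 rose, also over the list alone (p = 7.9e-30, and p = 4.5e-06 with an estimated correlation). That family was collected by orthology labels of VAMP72 or VAMP7 after the values were seen, so not every member is shown to be a VAMP72 gene. Its members may be similar enough to share reads, which was not checked, so values of single members are uncertain. The CST transgene itself was not analysed here.

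**Figure D1:**
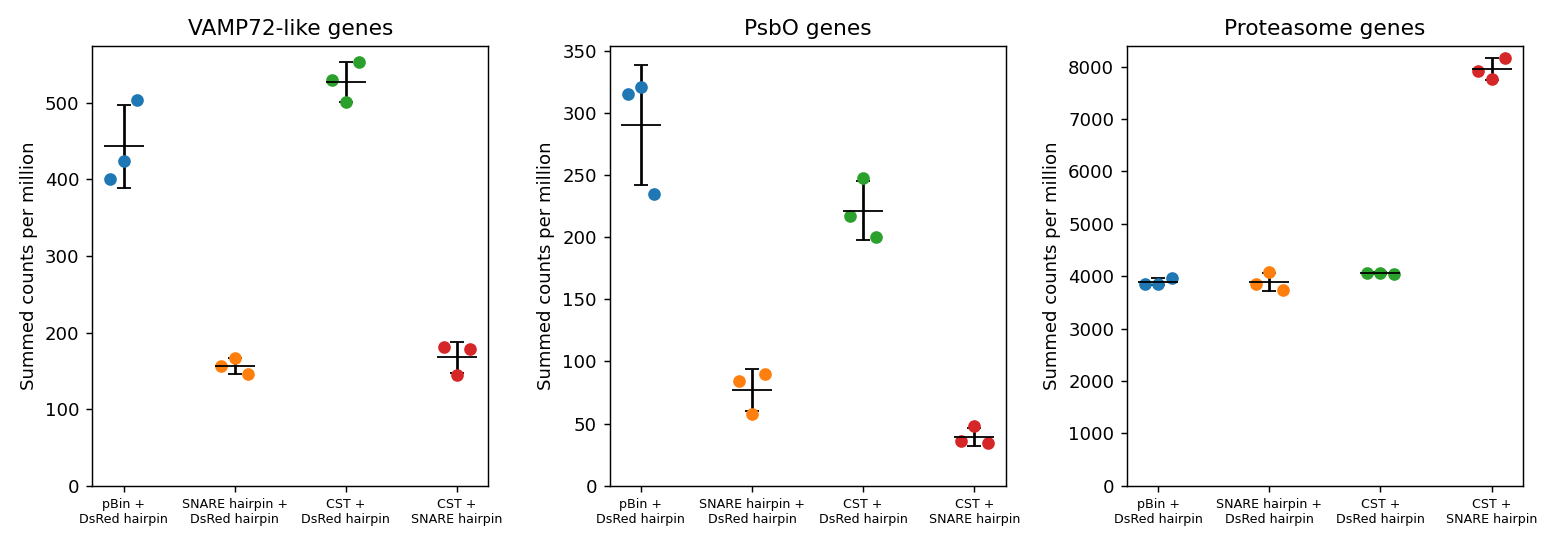
Summed CPM (y axis, from 0) of the VAMP72-like, PsbO and proteasome genes in each of the 4 groups (x axis), with a point per library and bars for the mean ± SD (n = 3). VAMP72-like genes averaged 156.2 and 167.9 in the groups with the SNARE hairpin against 442.8 and 527.3 without it. Proteasome genes averaged 7949 with CST and the SNARE hairpin against 3890 to 4059 in the other groups.

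The first comparison asked what the SNARE hairpin does where no CST is expressed. Beside the VAMP72-like genes, with NbS00060093g0001.1 at a log2 fold change of -2.35 ± 0.15 (SE, n = 3 per group, adjusted p = 2e-09), the 4 tested genes of the oxygen-evolving complex protein PsbO fell. Of 98 pathogenesis-related genes 7 rose (adjusted p = 0.14 for that list with an estimated correlation), and further genes outside these groups changed in either direction. PsbO3 (NbS00010454g0009.1) changed by -2.73 ± 0.21 and PsbO4 (NbS00027134g0004.1) by -2.46 ± 0.21. PsbO2 (NbS00019818g0001.1) and PsbO1 (NbS00032545g0003.1), added after the values were seen, changed by -1.94 ± 0.15 and -1.59 ± 0.22. Of the genes outside these families, a CbbY-like protein (NbS00019166g0007.1) fell by 3.82 on the log2 scale (adjusted p = 9.8e-11), from 37 to 2.59 RPKM. A U3 small nucleolar RNA-interacting protein (NbS00045685g0008.1, -2.38), a protein phosphatase 1 regulatory subunit (NbS00052111g0002.1, -2.29) and the vacuolar sorting protein VPS41 (NbS00025701g0010.1, -1.79 ± 0.14) also fell. So did the RPN6-like proteasome genes NbS00016436g0001.1 (-1.0) and NbS00048446g0001.1 (-0.94), chosen after their values were seen.

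The pathogenesis-related list had 7 genes higher and 0 lower, 15 and 0 adjusted over the list alone (camera, adjusted p = 0.0056 and adjusted p = 0.14 with an estimated correlation). Osmotin (NbS00026613g0001.1), an antifungal thaumatin-like protein, rose from 454 to 1190 RPKM (1.38 ± 0.19, adjusted p = 0.0011). Basic PR-1 (NbS00016396g0001.1) rose by 1.85 ± 0.33 and prb-1b (NbS00000664g0002.1) by 1.56 ± 0.32. A heme-binding-like protein (NbS00026545g0006.1, 1.99), an ascorbate peroxidase (NbS00010736g0008.1, 1.36), an ethylene-forming ACC oxidase (NbS00016384g0004.1, 0.9) and ERF5 (NbS00002094g0001.1, 1.27) rose. So did catalase 1 (NbS00013764g0007.1, 0.79) and the RNA-dependent RNA polymerase SDE1 (NbS00003024g0016.1, 0.63). ERF10 (NbS00055925g0001.1, -1.22), 5-epiaristolochene dihydroxylase (NbS00006716g0007.1, -0.55), a capsidiol enzyme, mevalonate kinase (NbS00023398g0009.1, -0.5) and an argonaute 5-like gene (NbS00011648g0011.1, -0.56) fell. The fixed VAMP7 and synaptobrevin list, which missed several VAMP72 genes, had 0 of 5 higher and 1 lower, 0 and 2 adjusted over the list alone (adjusted p = 1.2e-04 and adjusted p = 0.1 with an estimated correlation). Its other members did not pass. NbS00060422g0002.1 lay at -1.9 ± 0.66, NbS00001920g0005.1 at 0.13 ± 0.11, and the VAMP727-like NbS00012205g0001.1 and NbS00031641g0001.1 at -0.19 ± 0.24 and 0.23 ± 0.19. Terpene synthases (19 tested, no gene called), the mevalonate pathway (1 of 23 lower), capsidiol enzymes (1 of 22 lower), ABC transporters (1 lower, 4 adjusted over the list alone) and cell wall genes (1 higher and 1 lower of 151, 1 and 6 adjusted over the list alone) shifted down at adjusted p = 0.017, 0.017, 0.033, 0.015 and 0.013. WRKY factors (90 tested, no gene called) shifted up at 0.033. For those 6 lists adjusted p = 0.72 with an estimated correlation. As mean log2 CPM relative to the empty vector mean, SNARE hairpin replicates 1 to 3 lay at 0.04, 0.23 and 0.03 for WRKY factors, against 0.18 in empty vector replicate 3. For cell wall genes they lay at -0.14, -0.37 and -0.01 against -0.13 in that library, for terpene synthases at -0.22, -0.47 and -0.13, and for capsidiol genes at -0.08, -0.27 and -0.06, so replicate 2 stood apart in each of these lists.

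In all, 425 genes changed, 189 higher and 236 lower, of which 57 and 112 by 2-fold or more (edgeR, adjusted p threshold 0.05). The count was 1266 with no filter on low counts and 189 with limma-trend on RPKM values, 179, 211 and 229 without empty vector replicates 1, 2 and 3, 184 without SNARE hairpin replicate 3 and 802 without CST replicate 1. Each of the 6 compared libraries, left out, ended at least 1 of the calls of basic PR-1, prb-1b, ERF5, ERF10, catalase 1, the dihydroxylase, mevalonate kinase, SDE1 and the argonaute, with adjusted p of up to 0.13, 0.092, 0.17, 0.18, 0.1, 0.17, 0.2, 0.2 and 0.088; all of these but basic PR-1, and ACC oxidase, were also lost with limma-trend on RPKM values.

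The second comparison asked what CST does in leaves with the DsRed hairpin. Of 151 cell wall genes 51 fell and 5 rose, and of 22 genes of the tobacco phytoalexin capsidiol 12 fell. Of 90 WRKY factors, which regulate defence genes, 27 rose. With an estimated correlation these lists had adjusted p = 0.22, 0.11 and 0.22. The 5-epi-aristolochene synthase NbS00055581g0001.1, which makes the capsidiol precursor, changed by -1.23 ± 0.12 (SE, n = 3 per group, adjusted p = 5.1e-06), a related synthase (NbC23429524g0001.1) by -1.27 ± 0.2 and a premnaspirodiene oxygenase (NbS00019397g0002.1) by -1.16 ± 0.24. The capsidiol list had 12 genes lower and 0 higher, 14 and 0 adjusted over the list alone (adjusted p = 5e-16 and adjusted p = 0.11 with an estimated correlation). Of 19 terpene synthases 10 fell and 1 rose, 11 and 1 adjusted over the list alone (adjusted p = 3.5e-14, and 0.11 with an estimated correlation). The lists overlap in the aristolochene synthases.

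The cell wall list had 51 genes lower and 5 higher, 77 and 6 adjusted over the list alone (adjusted p = 2e-18 and adjusted p = 0.22 with an estimated correlation). CST replicate 1 stood apart for this list, at -0.91 in mean log2 CPM relative to the empty vector mean against -0.35 and -0.49 in replicates 2 and 3. Expansin-2 (NbS00020143g0013.1) changed by -1.63 ± 0.32 and a leucine-rich repeat extensin (NbS00000159g0002.1) by -2.11 ± 0.45 (-2.85 without CST replicate 2), while a pectinesterase (NbS00023392g0005.1) rose by 1.08 ± 0.3. The WRKY list had 27 genes higher and 0 lower, 31 and 1 adjusted over the list alone (adjusted p = 2.5e-10 and adjusted p = 0.22 with an estimated correlation), with a WRKY51-like gene (NbS00006279g0003.1) at 2.64 ± 0.43. Ethylene genes rose in 16 and fell in 4 of 125 cases, 23 and 9 adjusted over the list alone (adjusted p = 0.044, and 0.11 with an estimated correlation). ACC synthase ACS1 (NbS00020419g0111.1), which makes the precursor of ethylene, rose by 1.39 ± 0.26. The ERF012-like genes NbS00024429g0004.1 and NbS00015340g0002.1 changed by -1.62 and -2.18. Asparagine synthetases, which store nitrogen as asparagine, rose by 3.01 ± 0.45 (NbS00023526g0014.1) and 3.26 ± 0.78 (NbS00061472g0005.1), and by 2.31 and 2.14 without CST replicate 1. Rises were also found for a pathogenesis-related protein (NbS00013343g0015.1, 3.04 ± 0.8, and 1.66 without CST replicate 1), a lipoxygenase (NbS00001604g0013.1, 1.27), proteinase inhibitor 2 (NbS00017189g0001.1, 1.39) and SNAP33 (NbS00001631g0110.1, 0.75), a plasma membrane SNARE. In the mevalonate pathway 5 of 23 genes fell and 2 rose, 8 and 4 adjusted over the list alone, and the list did not pass (median -0.25, adjusted p = 0.088). The genes that rose were squalene epoxidase (NbS00044915g0003.1, 0.99) and HMG-CoA reductase (NbS00000653g0003.1, 0.59).

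Photosynthesis genes shifted down, with 8 lower and 3 higher of 134, the same numbers adjusted over the list alone (adjusted p = 0.0096 and adjusted p = 0.71 with an estimated correlation). Empty vector replicate 3 stood apart from replicates 1 and 2, at -0.26 against 0.17 and 0.09 in mean log2 CPM relative to the empty vector mean, within the CST libraries' -0.28 to -0.13. PsbS, which takes part in dissipating excess light, changed by -2.17 ± 0.43 (NbS00035687g0007.1, -2.82 without CST replicate 2) and -2.06 ± 0.39 (NbS00020769g0006.1). An early light-inducible protein (NbS00029310g0013.1) changed by -2.53 (-1.77 without empty vector replicate 3, -3.12 without CST replicate 2), the Calvin cycle regulator CP12 (NbS00011805g0001.1) by -2.44, the plastid glucose-6-phosphate translocator GPT2 (NbS00013256g0018.1) by -2.83 (-3.48 without CST replicate 2) and an ammonium transporter (NbS00012161g0011.1) by -2.51. Ribosomal protein genes (26 lower and 2 higher of 467, 4 and 1 adjusted over the list alone, adjusted p = 2.6e-05), cuticle genes (9 and 1 of 48, 12 and 3 adjusted over the list alone, 1.8e-04) and lipid transfer proteins (2 and 0 of 15, also over the list alone, 0.0049) shifted down. Among them were a GDSL esterase (NbS00024459g0004.1, -0.99) and a lipid transfer protein (NbS00005988g0001.1, -1.1). Senescence genes (8 of 25 higher, 9 adjusted over the list alone, adjusted p = 0.0011) and glutathione transferases (9 higher and 1 lower of 39, 13 and 3 adjusted over the list alone, 0.016) shifted up. Among them were a senescence-associated protein (NbS00016724g0009.1, 1.03) and a transferase (NbS00008099g0223.1, 1.03). With an estimated correlation the adjusted p of those 5 lists was 0.54, 0.22, 0.54, 0.49 and 0.54. In mean log2 CPM empty vector replicate 3 also lay within the range of the CST libraries for the ribosomal and lipid transfer lists. The VAMP727-like gene NbS00060093g0001.1 rose by 0.57 ± 0.12, a call lost with limma-trend on RPKM values (0.49).

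In all, 3651 genes changed, 1959 higher and 1692 lower, of which 420 and 522 by 2-fold or more. Scaling by library totals gave 1399 higher and 2327 lower, and limma-trend on RPKM values, which share that scaling, 850 and 1471. The count was 1432 without CST replicate 1, 1207 without empty vector replicate 1 and 1508 without empty vector replicate 2. Each of the 6 compared libraries, left out, ended at least 1 of the calls of the extensin, the pectinesterase, asparagine synthetase NbS00061472g0005.1, the pathogenesis-related protein, ACS1, GPT2, the early light-inducible protein, both PsbS genes, HMG-CoA reductase, the senescence-associated protein, the transferase and proteinase inhibitor 2, with adjusted p of up to 0.087, 0.18, 0.13, 0.15, 0.052, 0.075, 0.15, 0.06, 0.054, 0.054, 0.096, 0.062 and 0.076. CST replicate 1 lay farthest along the second principal component, at 68.8 against 29.1 and 39 for the other CST libraries.

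The third comparison set CST with the SNARE hairpin against CST with the DsRed hairpin. Of 104 proteasome genes 86 rose, and 11 of 20 VAMP72-like and 4 of 4 PsbO genes fell. Of 90 WRKY factors 45 fell and 8 rose, of 22 salicylate genes 10 fell and 1 rose, and of 134 photosynthesis genes 39 fell and 1 rose. With an estimated correlation these 3 lists had adjusted p = 0.23, 0.18 and 0.64. The proteasome list, added after the values were seen, had 86 genes higher and 3 lower, 88 and 3 adjusted over the list alone, with a median log2 fold change of 1.06 (camera p = 6.5e-69, and p = 2e-05 with an estimated correlation). The 20S core, annotated as the proteasome core complex, had 27 of 28 genes higher (median 1.39, adjusted p over 750 annotation terms 5.8e-50, and adjusted p = 0.019 with an estimated correlation). RPN2a (NbS00004643g0009.1) rose by 3.71 ± 0.21 (SE, n = 3 per group, adjusted p = 9.4e-11) and a tbp-1 interacting protein (NbS00046595g0010.1) by 3.55 ± 0.3. The RPN6-like genes NbS00016436g0001.1 and NbS00048446g0001.1 changed by -1.1 and -0.64.

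NbS00060093g0001.1 changed by -2.87 ± 0.15 (adjusted p = 3.7e-11), NbS00004447g0302.1 by -2.41 ± 0.14 and NbS00012174g0011.1 by -2.82 ± 0.21. Of the fixed VAMP7 and synaptobrevin list 2 of 5 fell and 1 rose, with the same numbers adjusted over the list alone (adjusted p = 0.033 and adjusted p = 0.19 with an estimated correlation). NbS00060422g0002.1 changed by -2.14 ± 0.59, a call lost without CST replicate 2 (adjusted p = 0.058). NbS00001920g0005.1 changed by 0.38 ± 0.11, a call lost without CST replicate 1 or CST and SNARE hairpin replicate 3 (adjusted p of up to 0.073). The median of this list was -0.14, and 0.01 after thinning. PsbO4, PsbO3, PsbO2 and PsbO1 (NbS00027134g0004.1, NbS00010454g0009.1, NbS00019818g0001.1, NbS00032545g0003.1) changed by -3.33, -2.78, -2.43 and -2.2. The CbbY-like gene NbS00019166g0007.1 changed by -3.63 and VPS41 (NbS00025701g0010.1) by -1.93. The WRKY list had 45 genes lower and 8 higher, 48 and 9 adjusted over the list alone (adjusted p = 1.1e-08 and adjusted p = 0.23 with an estimated correlation), with NbS00005295g0011.1 at -2.42 ± 0.27 and NbS00060127g0003.1 at -2.06 ± 0.23. Salicylate genes fell in 10 and rose in 1 of 22 cases, 12 and 1 adjusted over the list alone (adjusted p = 2.4e-04, and 0.18 with an estimated correlation). Among them were 2 copies of salicylic acid-binding protein 2 (NbS00007183g0012.1 and NbS00007183g0016.1), an esterase that releases salicylate, at -2.26 and -1.65. Pathogenesis-related genes fell in 26 and rose in 12 of 98 cases, 31 and 12 adjusted over the list alone (adjusted p = 0.041, and 0.19 with an estimated correlation; median -0.16, and 0.01 without photosynthesis and the 50 most abundant genes), with PR-1A (NbS00013421g0001.1) at -2.58 ± 0.54.

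Phenylpropanoid genes fell in 32 and rose in 8 of 92 cases, 34 and 10 adjusted over the list alone (adjusted p = 8.8e-04). Receptor-like kinases fell in 103 and rose in 25 of 354, 108 and 29 adjusted over the list alone (0.0014). Both had adjusted p = 0.18 with an estimated correlation. Phenylalanine ammonia-lyase 4 (NbS00007038g0001.1), the entry to phenylpropanoids, changed by -1.74 and a receptor-like kinase (NbS00022638g0012.1) by -2.33. Photosynthesis genes fell in 39 and rose in 1 of 134 cases, 41 and 1 adjusted over the list alone (adjusted p = 3.3e-06 and adjusted p = 0.64 with an estimated correlation), with plastocyanin (NbS00010560g0003.1) at -1.95. Cell wall genes rose in 37 and fell in 11 of 151 cases, 38 and 12 adjusted over the list alone (adjusted p = 0.034 and adjusted p = 0.75 with an estimated correlation). Their mean log2 CPM overlapped between the groups, with CST replicate 1 apart at -0.91 relative to the empty vector mean against -0.35 and -0.49 in replicates 2 and 3. The extensin NbS00000159g0002.1 rose by 3.45 ± 0.45 (4.17 without CST replicate 2) and the pectinesterase NbS00023392g0005.1 changed by -3.42. Squalene epoxidase (NbS00044915g0003.1) changed by -3.14 ± 0.17, a cysteine protease (NbS00003110g0006.1) by -4.49 ± 0.36, the dihydroxylase NbS00006716g0007.1 by -1.29 and the argonaute 5-like NbS00011648g0011.1 by -1.8. An inactive poly(ADP-ribose) polymerase-like gene (NbS00006519g0008.1, 4.0), a temperature-induced lipocalin (NbS00016847g0019.1, 3.33), a glucosyltransferase (NbS00030520g0003.1, 3.2) and sucrose synthase (NbS00022677g0026.1, 1.48) rose. So did a premnaspirodiene oxygenase-like gene (NbC25673618g0001.1, 2.17), an aristolochene synthase (NbS00013540g0011.1, 0.81) and SDE1 (NbS00003024g0016.1, 1.58).

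In all, 8207 genes changed, 3926 higher and 4281 lower, of which 1113 and 1416 by 2-fold or more. Scaling by library totals moved the median of all genes from 0.012 to 0.132 and gave 5891 higher and 3135 lower. Limma-trend on RPKM values, which share that scaling, gave 5453 and 2935. The proteasome median was 1.18 with library totals.

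The fourth comparison set CST with the SNARE hairpin against the SNARE hairpin with the DsRed hairpin. NbS00060093g0001.1 lay at 0.05 ± 0.18 (SE, n = 3 per group, adjusted p = 0.87) and NbS00004447g0302.1 at 0.44 ± 0.18 (adjusted p = 0.11), although the 3 libraries with CST lay above the others at 7.73 to 9.03 against 5.36 to 6.76 RPKM. Of the 20 VAMP72-like genes 1 fell, NbS00031386g0004.1 at -0.59 ± 0.14, chosen after its value was seen. Proteasome genes rose in 88 and fell in 0 of 104 cases, 91 and 0 adjusted over the list alone (median 1.05, camera p = 8.7e-90, and p = 5.3e-06 with an estimated correlation), RPN2a (NbS00004643g0009.1) by 3.92 ± 0.21. The CST and SNARE hairpin libraries are those of the third comparison, and the list was chosen after its values were seen. This rise is therefore no independent repeat of the earlier one. Photosynthesis genes fell in 65 and rose in 3 of 134 cases, 71 and 4 adjusted over the list alone (median -0.78, adjusted p = 1.2e-12 and adjusted p = 0.36 with an estimated correlation). Carbonic anhydrase (NbS00016159g0006.1), which supplies bicarbonate and carbon dioxide in the chloroplast, changed by -2.82 ± 0.75 (-2.13 without SNARE hairpin replicate 1). That call was lost without any of the CST and SNARE hairpin libraries or SNARE hairpin replicate 1 (adjusted p of up to 0.097). A chlorophyll a-b binding protein (NbS00054698g0008.1) changed by -2.08 ± 0.38. Tetrapyrrole genes fell in 7 of 23 cases with 0 higher, also over the list alone (adjusted p = 0.012, and 0.36 with an estimated correlation), among them the protochlorophyllide oxidoreductases NbS00012878g0025.1 and NbS00032371g0007.1, each at -1.46.

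Pathogenesis-related genes fell in 24 and rose in 8 of 98 cases, 25 and 8 adjusted over the list alone (adjusted p = 5.7e-04 and adjusted p = 0.15 with an estimated correlation), with PR10 (NbS00012812g0001.1) at -2.81 ± 0.3 and PR-1A (NbS00013421g0001.1) at -2.77 ± 0.54. WRKY factors fell in 26 and rose in 7 of 90 cases, 30 and 7 adjusted over the list alone (adjusted p = 0.0032, and 0.48 with an estimated correlation), with NbS00027540g0011.1 at -1.6. Lower shifts were also found for receptor-like kinases (76 lower and 28 higher of 354, 80 and 30 adjusted over the list alone, adjusted p = 0.0033), phenylpropanoid genes (26 and 5 of 92, 30 and 5, 0.0047), cuticle genes (15 and 0 of 48, 17 and 1, 0.0032), ribosomal protein genes (74 and 10 of 467, 44 and 9, 0.0032) and peroxidases (17 and 8 of 68, 20 and 10, 0.033). With an estimated correlation their adjusted p was 0.33, 0.36, 0.36, 0.56 and 0.36. Lipid transfer proteins fell in 6 and rose in 1 of 15 cases, also over the list alone (adjusted p = 0.0047, and 0.45 with an estimated correlation), with NbS00005988g0001.1 at -2.94 ± 0.29. Terpene synthases (6 of 19 lower, also over the list alone, adjusted p = 0.016) and capsidiol genes (9 lower and 2 higher of 22, 11 and 2 adjusted over the list alone, 0.036) shifted down, with adjusted p = 0.5 and 0.56 with an estimated correlation. For both lists SNARE hairpin replicate 2 lay within the range of the CST and SNARE hairpin libraries in mean log2 CPM. The aristolochene synthase NbS00004447g0101.1 changed by -0.69 ± 0.11.

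Senescence and autophagy genes rose in 13 of 25 cases with 0 lower, also over the list alone (adjusted p = 1.5e-05 and adjusted p = 0.36 with an estimated correlation), with ATG9 (NbS00055194g0003.1) at 1.0 ± 0.14. ATG8a (NbS00017537g0009.1), a protein of autophagosomes, rose by 1.27 ± 0.37, a call lost without CST and SNARE hairpin replicate 2 or SNARE hairpin replicates 1 or 2 (adjusted p of up to 0.056). Glutathione transferases rose in 10 and fell in 1 of 39 cases, 11 and 2 adjusted over the list alone (adjusted p = 0.0032, and 0.36 with an estimated correlation), among them parA (NbS00002272g0007.1, 2.18) and NbS00019895g0012.1 (2.25). Vesicle traffic genes rose in 36 and fell in 8 of 214 cases, 32 and 7 adjusted over the list alone (adjusted p = 0.015, and 0.36 with an estimated correlation), with RABA1f (NbS00010672g0009.1), a Rab GTPase, at 1.36. A glucosyltransferase (NbS00030520g0003.1, 5.31), the poly(ADP-ribose) polymerase-like NbS00006519g0008.1 (3.47), the lipocalin NbS00016847g0019.1 (3.14), CIG1 (NbS00041284g0005.1, 3.11, and 3.71 without SNARE hairpin replicate 2) and sucrose synthase (NbS00022677g0026.1, 1.57) rose. The cysteine protease NbS00003110g0006.1 (-3.13), squalene epoxidase (NbS00044915g0003.1, -2.1), isopentenyl diphosphate isomerase 2 (NbS00007783g0007.1, -0.87), a sucrose transporter (NbS00027087g0001.1, -1.44), catalase 1 (NbS00013764g0007.1, -1.34) and salicylic acid-binding protein 2 (NbS00007183g0012.1, -1.68) fell. In all, 7376 genes changed, 3694 higher and 3682 lower, of which 1002 and 1083 by 2-fold or more. Library totals gave 4328 higher and 3069 lower, limma-trend on RPKM values, which share that scaling, 3902 and 2668, and DESeq2 2867 and 3080.

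**Figure D2:**
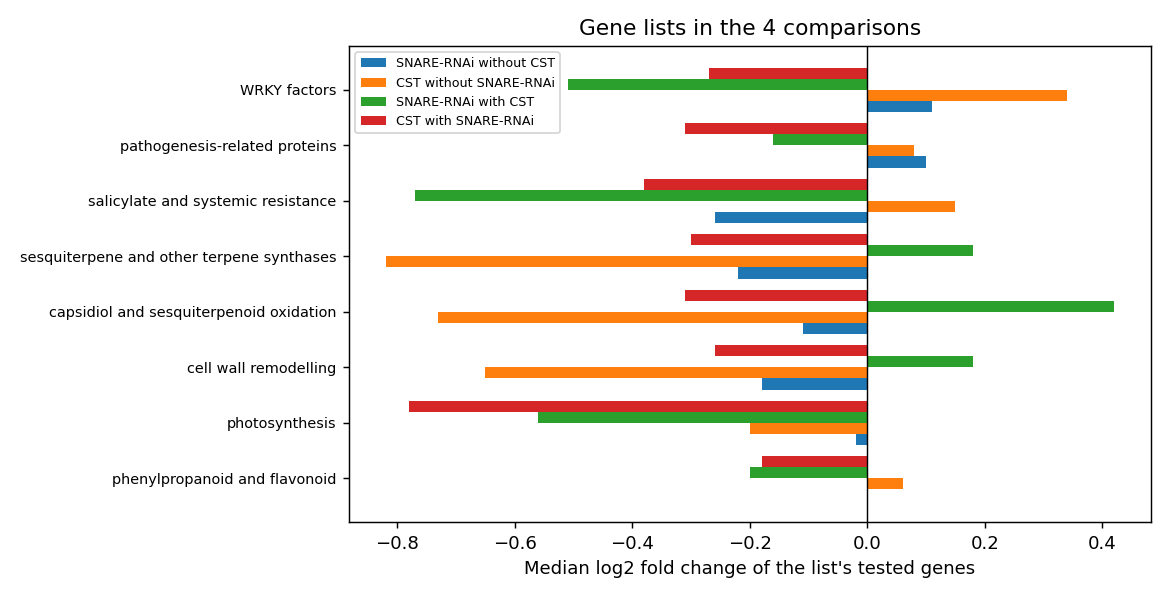
Median log2 fold change (x axis) of the tested genes of 8 fixed lists (y axis), with a bar per comparison. WRKY factors lay at 0.34 with CST and the DsRed hairpin against the empty vector and at -0.51 when the SNARE hairpin replaced the DsRed hairpin with CST. Photosynthesis genes lay at -0.78 with CST where the SNARE hairpin was present, and terpene synthases at -0.82 with CST where it was absent.

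Against the empty vector, CST and the SNARE hairpin together changed 8836 genes, 4378 higher and 4458 lower, of which 1121 and 1496 by 2-fold or more. Library totals gave 5114 higher and 3879 lower, and limma-trend on RPKM values, which share that scaling, 4594 and 3368. Proteasome genes rose in 85 and fell in 2 of 104 cases, 91 and 2 adjusted over the list alone (median 1.01, p = 1.1e-72, and p = 1.5e-05 with an estimated correlation). Photosynthesis genes fell in 66 and rose in 2 of 134 cases, 73 and 2 adjusted over the list alone (median -0.74, adjusted p = 1.7e-11 and adjusted p = 0.33 with an estimated correlation). Ribosomal protein genes fell in 112 and rose in 20 of 467, 113 and 20 adjusted over the list alone (adjusted p = 5.2e-04, and 0.52 with an estimated correlation).

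Whether the hairpin's effect differed with and without CST was tested as the interaction, which passed for 4930 genes, 2282 higher and 2648 lower. That contrast also contains the loss of the DsRed hairpin, so a differing hairpin effect cannot be told apart from that loss. Library totals gave 3299 and 1892, and limma-trend on RPKM values, which share that scaling, 2746 and 1459. Proteasome genes were higher in 77 and lower in 0 of 104 cases, 84 and 2 adjusted over the list alone (median 1.04, camera p = 1.3e-58, and p = 2.9e-05 with an estimated correlation). That result rests on the same CST and SNARE hairpin libraries as the proteasome rises above and adds no separate evidence. WRKY factors were higher in 1 and lower in 34 of 90, 1 and 41 adjusted over the list alone (adjusted p = 3.9e-11 and adjusted p = 0.23 with an estimated correlation). Both SNARE hairpin comparisons lowered 144 genes, against 32.1 for independent lists, and raised 51, against 23.6, while 67 moved in opposite directions. Their fold changes correlated at 0.062 across genes, and the comparisons share no library. Both CST comparisons raised 330 genes (230 for independent lists) and lowered 410 (198), with 504 in opposite directions. The SNARE hairpin and CST comparisons against the same empty vector libraries had 90 genes higher and 77 lower in common (11.8 and 12.7 for independent lists, 0 and 0 in simulated unchanged groups by edgeR). Their fold changes had a correlation of 0.484 against 0.496 simulated and a covariance of 0.079 against 0.033. Those that share the CST and SNARE hairpin libraries had 2395 and 2238 in common (460.9 and 500.9, and 0 and 0 simulated), with 0.75 against 0.506 and 0.268 against 0.0343. The simulated groups held no changed genes, so hardly any calls could arise there and 0 in common was set in advance. Those counts give no measure of what shared libraries add to the overlap of real calls. No split of the 3 shared libraries was made, and part of the excess may come from them.

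No fixed list passed with an estimated correlation in any comparison. Several lists passed in none of the 4 simple comparisons by camera with the preset correlation either. Their members are given for CST with the SNARE hairpin against CST with the DsRed hairpin, over all genes and then adjusted over the list alone. Other SNAREs rose in 7 and fell in 5 of 52 cases (7 and 5), plastid MEP pathway genes in 2 and 4 of 26 (2 and 4), jasmonate genes in 7 and 14 of 47 (7 and 14). UDP-glycosyltransferases rose in 18 and fell in 23 of 94 (21 and 29), cytochromes P450 in 15 and 32 of 121 (16 and 32), and heat shock proteins in 42 and 24 of 268 (42 and 24). Histone and cell cycle genes rose in 18 and fell in 4 of 87 cases (18 and 4), RNA silencing genes in 6 and 3 of 26 (6 and 3), calcium signalling genes in 27 and 54 of 181 (32 and 60), sugar transport genes in 5 and 10 of 55 (7 and 10) and aquaporins in 1 and 5 of 33 (1 and 5). Of the marker lists, meristem and root genes rose in 2 and fell in 3 of 24 cases (2 and 2), the guard cell list, which holds stomatin-like proteins, in 2 and 0 of 6 (2 and 0), and the virus list, which holds host proteins, in 2 and 2 of 20 (2 and 2). The trichome list had 1 tested gene, the phloem and xylem list 3 and the bacterial list 0, too few to test. Median, mean and test differed in sign for 33 of 210 combinations of list and comparison, 0 of which passed by camera. With other scalings the medians of some lists near 0 changed sign, 2 of them among the 66 called. By fry, which asks whether a list's genes move 1 way on balance and compares them with no other genes, 2, 7, 17 and 20 of 35 lists passed in the 4 simple comparisons, in the order above, against 8, 11, 8 and 15 by camera, and 2, 7, 7 and 13 by both. For CST with the SNARE hairpin against CST with the DsRed hairpin these include the MEP pathway (fry adjusted p = 0.02), cytochromes P450 (0.032), heat shock proteins (0.029), histones and cell cycle (0.021) and the guard cell list (1.5e-04).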

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

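The tests of RPN6-like genes and of the missing DsRed hairpin were chosen only after the results they address were seen, and so were those of read sharing, of silencing by the hairpin and of a single CST library. Thinning and the covariate were added after seeing the data. The interaction test passed for 4930 genes, and its contrast also contains the loss of the DsRed hairpin. A hairpin effect that differs with and without CST cannot be told apart from that loss. Of 100 regroupings of the 12 libraries 1, the real one, gave as many, and the highest of the others gave 1833. The bound set before for these regroupings does not decide, because the groups also differ in 425 to 8207 genes by the simple comparisons, and mixed groups carry those differences as spread. For the pairs of groups the 10 splits of 6 libraries are too few for a share under 0.05. The real split, fitted on those groups alone, gave 549, 3154, 7709, 7515 and 9800 genes for the SNARE hairpin without CST, CST without it, the SNARE hairpin with CST, CST with it, and both together. The highest other split gave 2, 0, 0, 0 and 0, with 1 split each, the real one, as large.

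By the same test the lists differed between the arms with a median log2 difference of 0.57 for terpene synthases, 0.59 for capsidiol enzymes, 0.36 for cell wall genes, -0.38 for pathogenesis-related proteins, -0.61 for WRKY factors, -0.3 for ethylene genes, -0.63 for salicylate genes, -0.28 for phenylpropanoid genes, -0.52 for photosynthesis, -0.49 for tetrapyrroles and -0.15 for receptor-like kinases. The camera adjusted p was 0.023, 0.0052, 3.5e-04, 3.5e-04, 3.9e-11, 0.039, 0.0052, 0.0014, 5.7e-05, 0.016 and 0.015, and 0.71, 0.67, 0.71, 0.12, 0.23, 0.18, 0.27, 0.23, 0.71, 0.49 and 0.23 as adjusted p with an estimated correlation. The genes with the smallest adjusted p of the interaction were an uncharacterized protein (NbS00004569g0028.1, -2.44), the proteasome ATPase ATSUG1 (NbS00011043g0012.1, 2.18), AER (NbS00015835g0003.1, -2.73), a predicted protein (NbS00022697g0001.1, -3.03) and arogenate dehydrogenase 2 (NbS00054171g0001.1, -2.79). Of 95 named genes 53 passed the interaction test, against 15.7% of the 31469 tested genes. Most named genes were picked for large changes in the simple comparisons, and 5 for their interaction p. A high share was therefore selected for and is no result about them. Of the 53, 12 were called with opposite signs, 11 for CST with and without the SNARE hairpin and 2 for the hairpin with and without CST. Catalase 1 was in both sets and PR10 in the latter alone. The counts of opposite signs depend on single libraries. With each of the 12 left out in turn, the set for CST held 3 (without CST replicate 1), 4 and 6 (without empty vector replicates 1 and 2) and 8 to 11 otherwise. The set for the hairpin held 0 without empty vector replicates 1 or 3 or SNARE hairpin replicate 3, and 1 without empty vector replicate 2, CST replicate 2 or CST and SNARE hairpin replicate 2. It held 2 otherwise, but not always the same genes. PR10 lost its opposite signs in 10 of the 12 fits, and in some of them another of the 12 genes took its place. The opposite signs held in each of these fits for the ERF012-like gene, squalene epoxidase and phenylalanine ammonia-lyase 4. Their differences were -2.05 for catalase 1 (NbS00013764g0007.1), -1.24 for the argonaute 5-like gene (NbS00011648g0011.1), 3.53 for the extensin (NbS00000159g0002.1), -3.09 for the pectinesterase (NbS00023392g0005.1) and for squalene epoxidase (NbS00044915g0003.1), 2.7 for an ERF012-like gene (NbS00024429g0004.1) and -4.25 for the cysteine protease (NbS00003110g0006.1). They were -2.32 for a WRKY factor (NbS00005295g0011.1), -2.17 for phenylalanine ammonia-lyase 4 (NbS00007038g0001.1), -2.16 for a receptor-like kinase (NbS00022638g0012.1), 4.41 for the lipocalin (NbS00016847g0019.1) and -2.51 for PR10 (NbS00012812g0001.1).

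Proteasome genes were higher with CST and the SNARE hairpin than in the other groups, at 7949 ± 210 summed CPM against 3890 to 4059 (SD, n = 3). After thinning all libraries to the lowest total, the median log2 fold change against CST with the DsRed hairpin was 1.05. This met the bound set against a lower depth of those libraries. Thinning keeps each gene's expected share of its library, however, so this median could hardly move. It therefore does not decide whether depth played a part. A fall of the RPN6-like genes NbS00016436g0001.1 and NbS00048446g0001.1 by itself is argued against. They changed by -1.0 and -0.94 without CST too. There the 100 proteasome genes other than the 4 RPN6-like ones had a median of -0.01 with an interquartile range of 0.27. Of all 104 proteasome genes 2 were lower without CST and 3 with it, so a fall of further genes is not covered. Absence of the DsRed hairpin cannot be told apart from the combination of CST and the SNARE hairpin, because 1 group lacks it and that group is the combination. A joint effect of CST and the SNARE hairpin may account for the pattern, as a hypothesis that was not tested apart from the missing hairpin.

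The genes lower in both SNARE hairpin comparisons include VAMP72-like, PsbO and CbbY-like genes. Reads moved among the tested VAMP72-like copies are argued against as the source of the VAMP72-like part. The summed CPM of these copies changed by -1.5 without CST and -1.65 with it on the log2 scale. That sum holds uniquely assigned reads of tested genes alone. Reads that went to other copies, or were no longer assigned uniquely, are not covered by it. Of 112 genes lowered 2-fold or more without CST 78 (69.6%) were lower again with CST, and of 57 raised genes 13 (22.8%) were higher again (Fisher's exact test, two-sided, p = 6.7e-09). Without the VAMP72-like and PsbO genes, left out after the values were seen, 65 of 99 (65.7%) and 13 of 57 (22.8%) recurred. The overlap of these calls had been seen before, and genes of 1 family are not independent, so that p restates the pattern and is no evidence for its source. Silencing by the hairpin itself and a response to the loss of VAMP72 would both make genes recur. They cannot be told apart here, because the sequences needed to separate them were not analysed.

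The CST effect without the SNARE hairpin ran along a direction in which libraries of 1 group also differ. With the score of each library on the first within-group component of the SNARE hairpin groups as a covariate, 1035 genes changed in place of 3651 and the cell wall median moved from -0.65 to -0.41. The bounds set for and against a leaf-to-leaf axis each asked for both a count and a median, and neither was met. The scores also separate the compared groups, at -1.09, -0.44 and -0.66 with CST against 1.03, 0.8 and -0.06 in the empty vector. Such a covariate takes calls away whatever their source, so the lower count is no evidence for that axis, which remains open. Leaving out CST replicate 1 gave 1432 genes, which met the bound set for a single library as the source. Leaving out empty vector replicate 1 gave 1207, so the fall is not particular to a CST library; this explanation was left open after those values were seen, as is a CST effect itself.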

How the results depend on the processing

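Library-total scaling and thinning to the lowest total were chosen after seeing the data. Counts of changed genes are given in the order SNARE hairpin without CST, CST without it, SNARE hairpin with CST, CST with it, both together, interaction. A 2-fold minimum gave 169, 942, 2529, 2085, 2617 and 2418, fewer by construction. For the SNARE hairpin without CST the replicate block gave 263 in place of 425, no filter on low counts 1266, and limma-trend 189 on log2(RPKM + 0.5) and 172 on log2(RPKM + 0.1). For CST without the hairpin limma-trend gave 2321 and 2179 in place of 3651. The cause was not tested. Leaving out 1 library gave 179 (without empty vector replicate 1) to 802 (without CST replicate 1) for the former and 1207 (without empty vector replicate 1) to 4128 (without empty vector replicate 3) for the latter. Other counts stayed within 1.5 times the main one, and no named gene that passed reversed. The VAMP727-like gene NbS00060093g0001.1, not called for CST with the hairpin, ran from -0.08 to 0.17 with 1 library left out. The side with more genes turned under at least 1 scaling in every comparison but the SNARE hairpin without CST. With upper-quartile scaling CST without the hairpin went from 1959 higher and 1692 lower to 1681 and 1859, the SNARE hairpin with CST from 3926 and 4281 to 4325 and 3995, and the interaction from 2282 and 2648 to 2469 and 2449. CST with the hairpin went from 3694 and 3682 to 2867 and 3080 with DESeq2, and both together from 4378 and 4458 to 5114 and 3879 with library totals. Of 66 called lists 2 had a median of the other sign under a scaling, both for the SNARE hairpin with CST: the VAMP7 list (0.01 after thinning) and pathogenesis-related genes (0.01 without photosynthesis and the 50 most abundant genes). Small changes are often missed: on simulated counts 5% to 26.8% of log2 changes of 0.5 were called. Depth was not varied in that simulation, so its part in this was not tested.

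The replicate block gave 2823, 7524, 6612, 8097 and 4175 genes for the other 5 comparisons. It ended 9 calls of named genes: ERF5, the dihydroxylase, mevalonate kinase and SDE1 for the SNARE hairpin without CST, the pectinesterase, the pathogenesis-related protein, GPT2 and the early light-inducible protein for CST without it, and carbonic anhydrase for CST with it. It ended the capsidiol call for CST with the hairpin (adjusted p = 0.053), and peroxidases passed for CST without it (0.049). Limma-trend on log2(RPKM + 0.5) ended 10 calls of named genes: prb-1b, ACC oxidase, ERF5, ERF10, catalase 1, the dihydroxylase, mevalonate kinase, SDE1 and the argonaute for the SNARE hairpin without CST, and the rise of NbS00060093g0001.1 for CST without it. The numbers do not pair the samples: same-numbered libraries of different groups deviated with correlations of -0.24 to 0.16 (mean -0.04, 2 of 18 over 0.1), and 1 library correlated best with its own number.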

Other observations

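The scan of annotation terms was chosen only after the results were seen. With CST and the DsRed hairpin, genes of cellulose synthase activity fell in 15 of 28 cases and those of starch metabolism in 19 of 56 with 1 higher, while phenylalanine metabolism genes rose in 11 of 27 (adjusted p = 5.5e-14, 1.4e-08 and 5.5e-06, and adjusted p = 0.68 with an estimated correlation for each). With CST where the SNARE hairpin was present, carbon fixation genes fell in 27 of 37 cases (median log2 fold change -0.97, adjusted p = 4.1e-12 and adjusted p = 0.63 with an estimated correlation) and photosystem I genes in 16 of 29 (median -0.93, adjusted p = 1.1e-07, and 0.64 with an estimated correlation). Terms that also passed with an estimated correlation there were 3 proteasome terms, modification-dependent protein catabolism (114 higher and 11 lower of 284, adjusted p = 0.037 with an estimated correlation), endopeptidase activity (75 and 42 of 310, 0.037) and the extracellular matrix (0 and 7 of 10, 0.037). Of 750 terms 0, 0, 1 and 6 passed with an estimated correlation for the SNARE hairpin without CST, CST without it, the SNARE hairpin with CST and CST with it.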
